A study of Arabidopsis thaliana with 6 samples.

How the data were processed

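Chromatin and RNA came from young leaves of *Arabidopsis thaliana* Columbia-0 plants grown in soil in short days (8 h light, 16 h dark, 22.5 °C). Per the labels' protocols, libraries were made from 20 ng of immunoprecipitated or input DNA or 1 ug of total RNA and sequenced on an Illumina Genome Analyzer IIx. Groups were taken from the sample titles: 2 H3K4me3 ChIP, 2 H3K27me3 ChIP, 1 input DNA and 1 mRNA sample. Bowtie, SICER and the TAIR10 genome build are named in the submitters' processing notes, without versions or settings. How the 2 replicates of a mark and the input entered the domain calls is not given in the sources used here.

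The authors deposited 1 list of domains per mark for the whole series, with a chromosome, a start, an end and a whole-number score per domain. The unit of this score is not given in the sources used here. It rose with domain width (Spearman rho 0.89 for H3K4me3 and 0.95 for H3K27me3) and was used only to rank domains within a list. Starts and widths were multiples of 150 bases for H3K4me3 and of 300 for H3K27me3, and the end column gave the last base, so 1 was added to each start and end for printing. For mRNA the authors deposited a coverage signal, the mean read depth over the exons of each gene. The lowest value was exactly 1, given to 7.66% of the listed genes, so the mean appears to be taken over bases with at least 1 read. Library size, reads per gene and any scaling are not given in the sources used here, so depths rank genes within this library and the sampling error of a single depth is unknown. The 10 deepest genes held 14.3% of the summed depth. The plan had assumed read counts, scaled by exon length. Since the values were depths, they were used as deposited for classes and lists, and a minimum of 10 reads could not be applied.

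Gene names, loci and gene bodies came from the RefSeq gene table of assembly TAIR10.1, which has no strand or exon lengths. TAIR10.1 and TAIR10 differ in name. Gene bodies were still used for overlaps, because their nuclear chromosomes are, to general knowledge, the same sequence, and because a check on the data found no offset. In each of 24 windows of 5 Mb, the H3K4me3 domains fitted the gene bodies best at a shift of 0 among shifts up to 10 kb in steps of 50 bases. No gene coordinate of that table is printed, and printed coordinates are those of the domains, 1-based in TAIR10. Of 20764 loci in the mRNA table, 20677 matched a locus on the nuclear chromosomes and 87 did not. The reference holds loci annotated later, which the mRNA table cannot list. Reads of overlapping genes cannot be separated here, because whether strand was used is not given in the sources used here.

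A gene carried a mark when domains covered at least 150 bases of its body, or all of it if shorter. The association of the marks was the odds ratio over 27444 protein-coding genes, tested by 1000 circular shifts of the H3K27me3 labels along gene order within chromosomes. Shared bases were tested by 1000 circular shifts of the H3K27me3 domains along each chromosome. Both tests were two-sided, with 0.002 as the smallest p. Lists with at least 5 members were tested by Fisher's exact test per mark, adjusted over 30 tests by the Benjamini-Hochberg method with a threshold of 0.05. With 1 mRNA library, the depth of classes and lists was only described, by medians, quartiles, shares listed, Spearman rho across genes, and percentiles among 10000 random lists matched in 20 bins of gene length. H3K27me3 on genes grouped by depth was compared by Fisher's exact test in the closing section, which counts genes of 1 library and no replicates. The pseudocount on the log2 scale was 1. Intervals are 95%, exact Clopper-Pearson for shares and from order statistics for medians. List members were written from general knowledge as locus identifiers, all 202 of which were in the reference table. For 7 the usual symbol was not in that table.

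Values of 1 list member and 1 gene family are not reported here. The genes named were set by a rule before the data were examined. In each list these were the 2 deepest and 2 shallowest members (ties by locus), and members outside the most frequent class were allowed, of which some are named. Added were the 5 widest domains per mark, the 5 genes with the most bases under both marks, the 5 deepest genes per class and the 5 unlisted genes with the widest H3K4me3 alone. Further list members named as examples, the 3000-base limit for wide domains, the percentile bins of depth, the gene density bins and the older-name check were chosen after seeing the data.

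The tests were checked on simulated data built on the 27444 genes. In 100 simulations, H3K27me3 labels were drawn without regard to H3K4me3, each gene depending only on the gene before it, with the observed share and persistence on each chromosome. At 0.05 the shift test called 6% of them and Fisher's exact test 5%. Among 100 rotations of the observed labels, which keep longer runs, Fisher's exact test called 14%. With 25% of the genes with both marks removed (median odds ratio 0.67), the shift test called 100% of 50 simulations built on such rotations. For the list test, 92% of 200 simulated lists of 15 genes with a planted 80% H3K27me3 share were called, and 0.5% of 400 random lists.

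The alternatives were other limits for a mark on a gene (1 base, 50% of the body), domains at or above the median score, leaving out genes that overlap another gene, listed genes only, a pseudocount of 0.1, 50% of the shorter domain as overlap, the share of the body covered in place of bases, and the other test where there were 2. H3K27me3 domains of at least 600 bases, H3K27me3 domains at or above the median score of their width (3000 bases or more as 1 group), a depth of at least 2 and genes with an older name were added after seeing the data. A gene start inside a domain could not be used without strand. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used.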

Results

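The series profiled 2 histone modifications and mRNA in young leaves of *Arabidopsis thaliana* Columbia-0 plants kept in short days of 8 h light and 16 h dark at 22.5 °C. Trimethylation of histone H3 at lysine 4 (H3K4me3) is a mark of transcribed genes, and trimethylation at lysine 27 (H3K27me3) is set by Polycomb Repressive Complex 2 (PRC2). There were 2 chromatin immunoprecipitation (ChIP) samples for each mark, 1 input DNA sample and 1 mRNA sample, 6 in all. The files used here hold 1 list of enriched domains per mark and 1 table of mean read depth per gene. The spread between ChIP replicates could therefore not be measured, the number of ChIP reads is unknown, and no value below has a replicate error. The mRNA table listed 20764 genes with depths from 1.00 to 22244.1 and a median of 6.74, and no gene was listed under 1. Of 27444 protein-coding genes on the 5 nuclear chromosomes, 72.9% were listed. Genes that were not listed were set to a depth of 0, which means only that no depth was given for them. The 95% intervals on shares are exact Clopper-Pearson intervals and, like those on medians, cover counting error over genes only.

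The design sets the distribution of the 2 marks along the genome side by side. H3K4me3 formed 19276 domains that covered 14.99 Mb, 12.6% of the 119.14 Mb spanned by the data. H3K27me3 formed 15863 domains that covered 18.0 Mb, 15.1% of that span. H3K4me3 lay on genes, with 95.6% of its bases inside protein-coding gene bodies, which make up 54.1% of the span. For H3K27me3 that share was 54.6%. H3K4me3 domains were short and even, with a median of 750 bases (quartiles 600 and 900) and a maximum of 4950. H3K27me3 domains had a median of 900 bases (quartiles 600 and 1500) and reached 24900. Domains of 3000 bases or more numbered 875 for H3K27me3, 5.52% of the list, against 11 for H3K4me3, 0.0571%. The H3K4me3 list was called in 150-base steps and the H3K27me3 list in 300-base steps, so the narrowest possible domains differ between the marks. Both marks were present on each chromosome, with H3K4me3 on 11.4% to 13.0% and H3K27me3 on 14.5% to 15.5% of the bases. H3K4me3 rose with gene density while H3K27me3 was highest in bins with fewer genes than most but not the fewest. In bins of 1 Mb in 5 groups from the 24 poorest to the 24 richest in genes, H3K4me3 covered 3.42%, 10.9%, 14.6%, 15.7% and 18.3% of the bases, and H3K27me3 covered 12.9%, 18.3%, 16.6%, 15.2% and 12.6%.

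**Figure D1:**
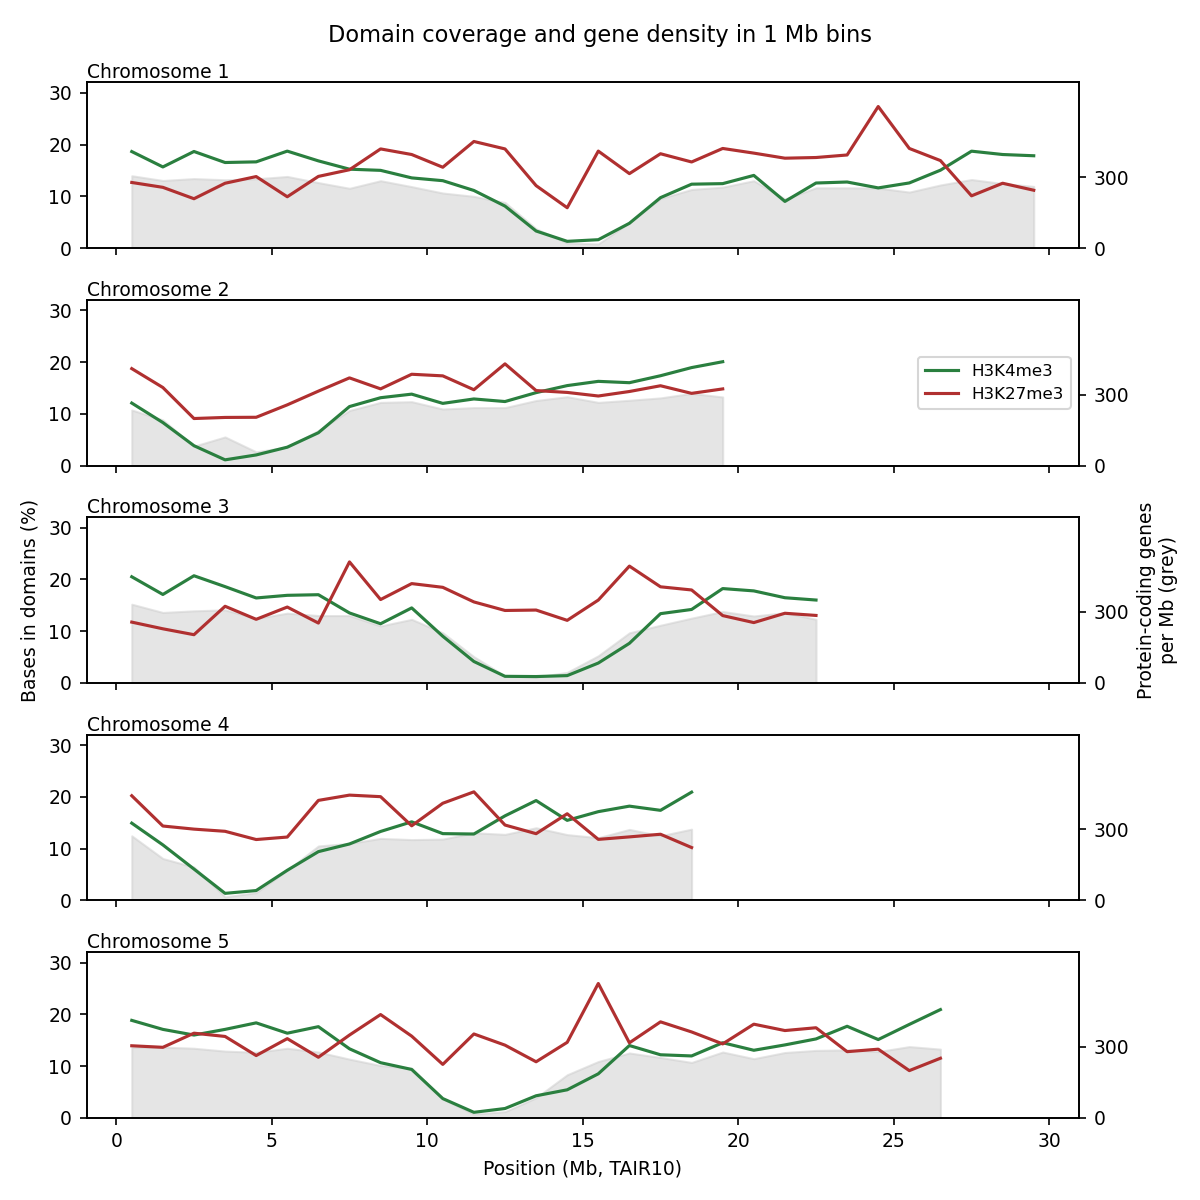
Percent of bases in H3K4me3 domains (green) and H3K27me3 domains (red) in consecutive 1 Mb bins of the 5 nuclear chromosomes, left axis, with position in Mb (TAIR10) below. The grey area is the number of protein-coding genes per Mb, right axis. H3K4me3 follows gene density, whereas H3K27me3 covers 12.9% of the gene-poorest 24 bins together, 18.3% of the next 24 and 12.6% of the richest 24.

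Of the 5 widest H3K4me3 domains, 4 covered genes listed in the mRNA table. The widest, 4950 bases on chromosome 1 (22034551 to 22039500, TAIR10), covered PEN3, an ABC transporter of pathogen defence with a depth of 83.7. Next came 3750 bases on chromosome 5 (4388551 to 4392300) over GUN5, the H subunit of magnesium chelatase in chlorophyll synthesis, at a depth of 794.9. A domain of 3600 bases on chromosome 4 (15927751 to 15931350) covered GLDP1, the photorespiratory glycine decarboxylase P protein, at 538.4. The fourth, 3450 bases on chromosome 1 (5444401 to 5447850), covered AT1G15810 and LHCB6, a photosystem II antenna protein at a depth of 4288. The fifth, 3300 bases on chromosome 1 (29806201 to 29809500), touched no protein-coding gene and lay on the pseudogene AT1G79245. The widest H3K27me3 domains were of another kind. Of the 5 widest, 4 touched no protein-coding gene. These were 24900 bases on chromosome 1 (15114001 to 15138900), 18600 on chromosome 5 (11930101 to 11948700, with 3 loci annotated as pseudogenes and MIR854e), 17400 on chromosome 4 (2920501 to 2937900) and 15600 on chromosome 3 (14173801 to 14189400). The other, 19500 bases on chromosome 1 (16509601 to 16529100), spanned AT1G43730 and AT1G43760, neither of them listed in the mRNA table, and 4 loci annotated as pseudogenes.

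The marks overlapped less than shifted positions did. They shared 1525 kb, whereas circular shifts of H3K27me3 along each chromosome gave 2268 ± 44.8 kb (SD over 1000 shifts), a ratio of 0.673. The two-sided p of 0.002 was the smallest that the shifts can give. The overlap was still sizeable in number, since 3148 H3K4me3 domains (16.3%) touched an H3K27me3 domain and 2118 of them lay wholly inside it. In the other direction 3023 H3K27me3 domains (19.1%) touched H3K4me3. Among domains scoring at or above the median of their list, the touching H3K4me3 domains numbered 230 and the ratio fell to 0.221.

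Protein-coding genes were then sorted by mark, a gene carrying a mark when domains covered at least 150 bases of its body. H3K4me3 alone was found on 14886 genes (54.2%), H3K27me3 alone on 5714 (20.8%), both on 2785 (10.15%) and neither on 4059 (14.8%). Fewer genes carried both marks than the 5472 ± 47.5 (SD) given by shifting H3K27me3 along the gene order. H3K4me3 was present on 32.8% of the genes with H3K27me3 and on 78.6% of those without. The odds ratio was 0.133 (95% interval 0.126 to 0.141), against 0.824 to 1.14 over 1000 shifts, with the smallest two-sided p of 0.002. Per chromosome it ranged from 0.125 to 0.156. H3K27me3 covered a median of 82.4% of the body of genes with that mark alone, and H3K4me3 32.5% of the body of genes with H3K4me3 alone.

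The number of genes with both marks depended on how a mark was called. It was 410 when domains had to cover at least 50% of the gene body and 276 with domains at or above the median score, and the odds ratio was 0.330 and 0.0607 under these settings. Genes with H3K4me3 alone fell to 3854 and 9594, and genes with neither rose to 17523 and 11926. On 91.2% of the genes with both marks, the marks shared at least 150 bases, with a median of 450. The most shared bases, 2850, were found on AT3G22125 and AT3G22142, which overlap each other and are not independent. NIA2 (AT1G37130), a nitrate reductase with a depth of 298.0, had 2700 bases under both marks, and GUN5 had 2400. AT5G17980, with a depth of 1.58, had 2250. NIA2, GUN5 and AT5G17980 also carried both marks among domains at or above the median score, and the overlapping pair carried only H3K27me3 there.

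mRNA depth followed the marks. Genes with H3K4me3 alone had a median depth of 8.93 (95% interval 8.71 to 9.15), and 98.2% of them were listed (97.9 to 98.4). Genes with H3K27me3 alone had a median of 0, and 26.0% were listed (24.9 to 27.2). Genes with both marks lay between, with a median of 2.36 (2.17 to 2.61) and 79.0% listed (77.4 to 80.5). Genes with neither mark had a median of 0 and 41.8% listed (40.3 to 43.3). With 50% of the body as the limit, that class was larger and had a median of 4.58 and 81.5% listed, above the 2.92 and 77.8% of genes with both marks, and with domains at or above the median score it had 1.86 and 69.7%. Of the 2363 unlisted genes with neither mark, 53.0% (51.0 to 55.1) had no older clone-based name in the reference table. Such a name was also missing for 24.4% (22.3 to 26.5) of the 1696 listed genes with neither mark. A missing older name alone therefore does not show that a locus was annotated later. Loci annotated after the mRNA table was made cannot be listed in it. Genes with neither mark and an older name had a median of 1.00 and 53.6% listed. Mean log2(depth + 1) was 3.07 higher with H3K4me3 alone than with H3K27me3 alone, and the share listed was 72.2 percentage points higher. Each class median was set among 10000 random gene lists of the same size and gene length. The median for H3K4me3 alone stood at percentile 100, above a random median of 4.75. The medians of the other classes stood at percentile 0, below 1.91, 3.72 and 1.00. Lists this large vary little, with 95% of random medians from 4.65 to 4.86 for H3K4me3 alone. The percentiles therefore add little to the medians themselves. No p-value is given for the differences in depth between classes because there was 1 mRNA library. The difference in mean log2 values was 1.92 among listed genes only and 5.43 with a pseudocount of 0.1, and among domains at or above the median score the genes with both marks had a median of 9.56.

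**Figure D2:**
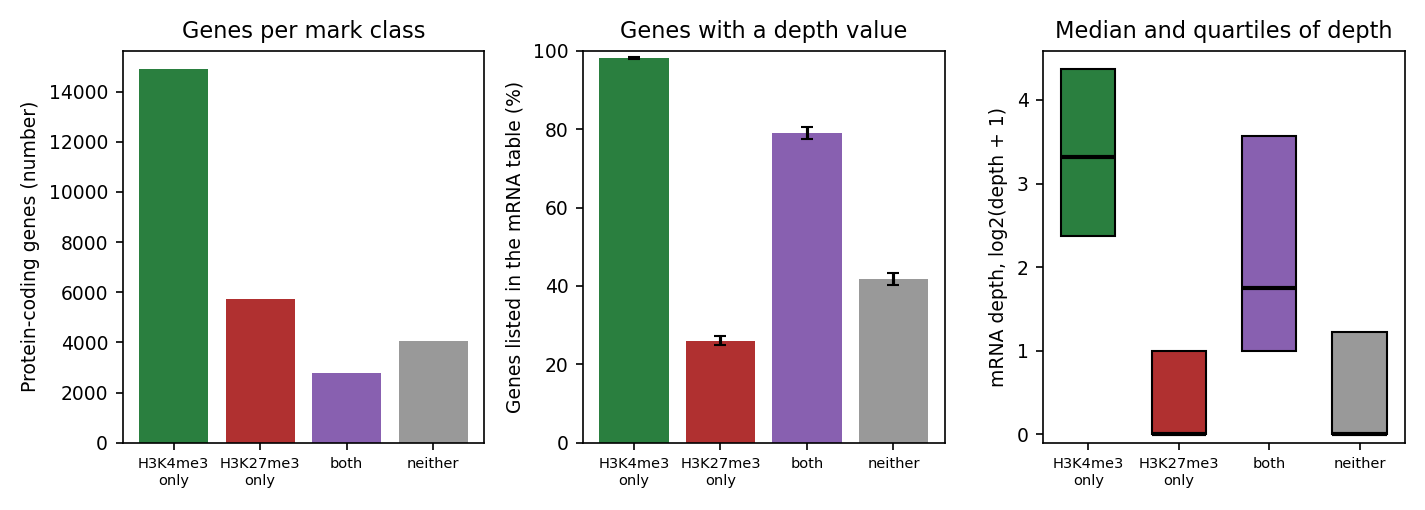
Left, number of protein-coding genes per mark class. Middle, percent of each class listed in the mRNA table, with exact 95% intervals as error bars. Right, log2(depth + 1) per class, where the box spans the quartiles and the thick line is the median, unlisted genes counting as 0. Genes with H3K4me3 alone are listed in 98.2% of cases and genes with H3K27me3 alone in 26.0%.

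The deepest genes with H3K4me3 alone were photosynthesis genes: CAB1 (AT1G29930, 22244 in depth), RBCS1A (AT1G67090, 12915), LHB1B2 (AT2G34420, 10377), CAB2 (AT1G29920, 8364) and LHCB3 (AT5G54270, 6628). CAB and RBCS genes are near-identical copies whose reads can be split between them, so their single values are uncertain, and CAB1, LHB1B2 and LHCB3 also overlap another annotated gene. Among genes with H3K27me3 alone the deepest was TGG1 (AT5G26000), a myrosinase that cleaves glucosinolates, at 1029. It lay wholly under H3K27me3, and its neighbour TGG2 (AT5G25980), also a myrosinase, had a depth of 371.3 with 94.2% of its body under the mark. AT1G67865 (383.3), AT1G23130 (375.1) and AT1G64370 (321.8) completed this group. All 5 also carried H3K27me3 in domains at or above the median score. Such genes were rare, since 1.89% of the genes with H3K27me3 alone reached a depth of 10, against 45.9% of those with H3K4me3 alone. The deepest genes with both marks were CAB3 (10871), LHCA3 (6006), LHCB6 (4288), PSAD-1 (3567) and the extensin-like gene ELP (1859), with LHCB6 overlapping another gene. None of these 5 kept H3K27me3 among domains at or above the median score. Without either mark the deepest genes were the metallothionein gene MT1A (490.8), AT2G01021 (297.4), AT5G35480 (281.3), AT1G19550 (104.1) and AT4G00780 (88.5), of which MT1A and AT1G19550 overlap another gene.

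Of the genes with H3K4me3 alone, 274 were not listed in the mRNA table. The widest H3K4me3 coverage among them was on AT5G03355 with 1650 bases, followed by AT1G72275 and AT3G02645 with 1350, AT2G44993 with 1339 and AT2G11035 with 1331, the last 2 of which overlap another gene. These 5 loci have no older clone-based name in the reference table. Such names were missing for 67.2% (61.2 to 72.7) of the 274 unlisted genes and for 13.7% (13.2 to 14.3) of the listed genes with H3K4me3 alone, and a locus annotated after the mRNA table was made cannot be listed in it. Of the 274, 51.1% overlap another annotated gene, against 34.9% of the listed genes with H3K4me3 alone. Where bodies overlap, H3K4me3 in the shared part cannot be assigned to a single gene.

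Coverage by a mark and depth were also compared across genes, which are not independent replicates. More H3K4me3 on a gene went with deeper mRNA, with a Spearman rho of 0.76 between covered bases and depth over all genes and 0.45 among the 17671 genes with the mark. More H3K27me3 went with shallower mRNA over all genes, at a rho of -0.47, but the relation was weak among the 8499 genes with the mark, at -0.095. It was -0.27 among listed genes only. Genes with each mark were also split into 5 equal groups by the share of the body covered. For H3K4me3 the median depth rose from 4.70 (4.45 to 4.89) in the lowest group to 14.2 (13.4 to 15.4) in the highest. For H3K27me3 the share of listed genes fell from 74.6% in the lowest group, where a median of 21.9% of the body was covered, to 15.6% in the highest, where it was 100%. Along mRNA depth, H3K27me3 was on 51.9% (49.7 to 54.1) of the shallowest 10% of listed genes and on 8.99% (8.27 to 9.74) of the genes between the 50th and 80th percentile. It was on 22.5% (16.9 to 28.9) of the 200 deepest. Among domains at or above the median score, it was on 7.50% (4.26 to 12.1) of these 200. The genes between the 50th and 80th percentile then had it in 4.05% (3.57 to 4.58) of cases.

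**Figure D3:**
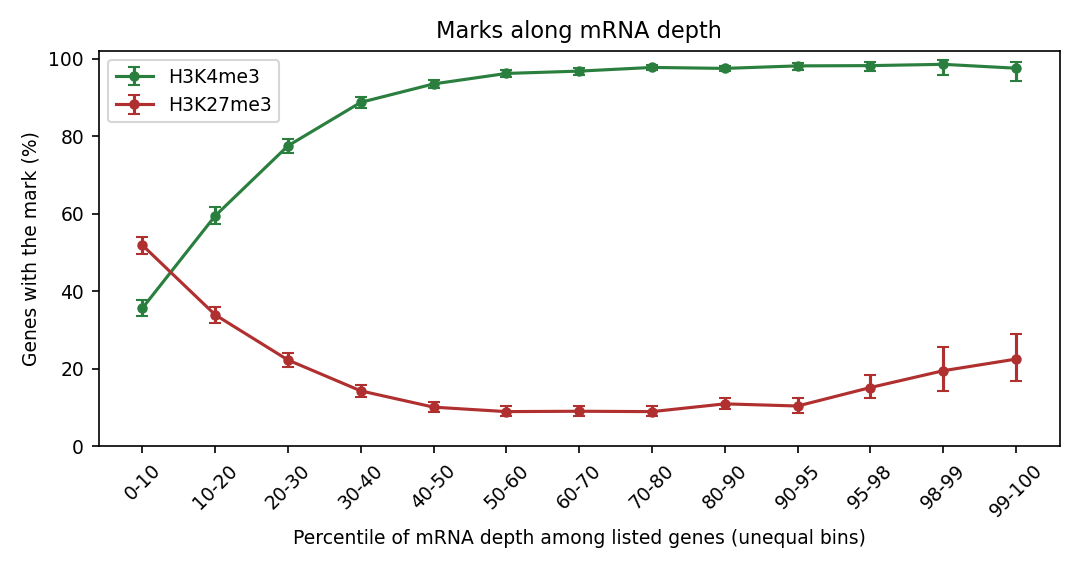
Percent of listed protein-coding genes that carry H3K4me3 (green) or H3K27me3 (red), by percentile of mRNA depth, in bins of unequal size. Error bars are exact 95% intervals. H3K27me3 falls from 51.9% of the shallowest genes to 8.99% in the middle and stands at 22.5% of the deepest.

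To describe which gene groups carried each mark, 16 gene lists with 202 genes were fixed before the data were examined. All 202 were found among the protein-coding genes. Fisher's exact test, two-sided, compared the 15 lists with at least 5 members with all other genes for each mark, and p-values were adjusted over the 30 tests by the Benjamini-Hochberg method (exact adjusted p). H3K27me3 was more frequent in 6 lists and less frequent in 1, and H3K4me3 more frequent in 3 and less frequent in 2. Among other genes, about 31.0% carried H3K27me3 and 64.4% carried H3K4me3. Some list members are tandem neighbours under shared domains (SESA1 to SESA4, for example), which Fisher's test treats as independent. Of the members named below, AT5G60390, ASHH2, CLF, CO, DUO1, ELF6, ESB1, EXPA7, FIS2, FLC, GEX2, GL2, GL3, GRF3, JMJ14, JMJ18, KAN1, LHP1, MSI1, REV and RING1B, besides CAB1 and LHCB6, overlap another annotated gene, whose reads cannot be separated from theirs here. All 12 calls also held when mark labels were shifted along the gene order.

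**Figure D4:**
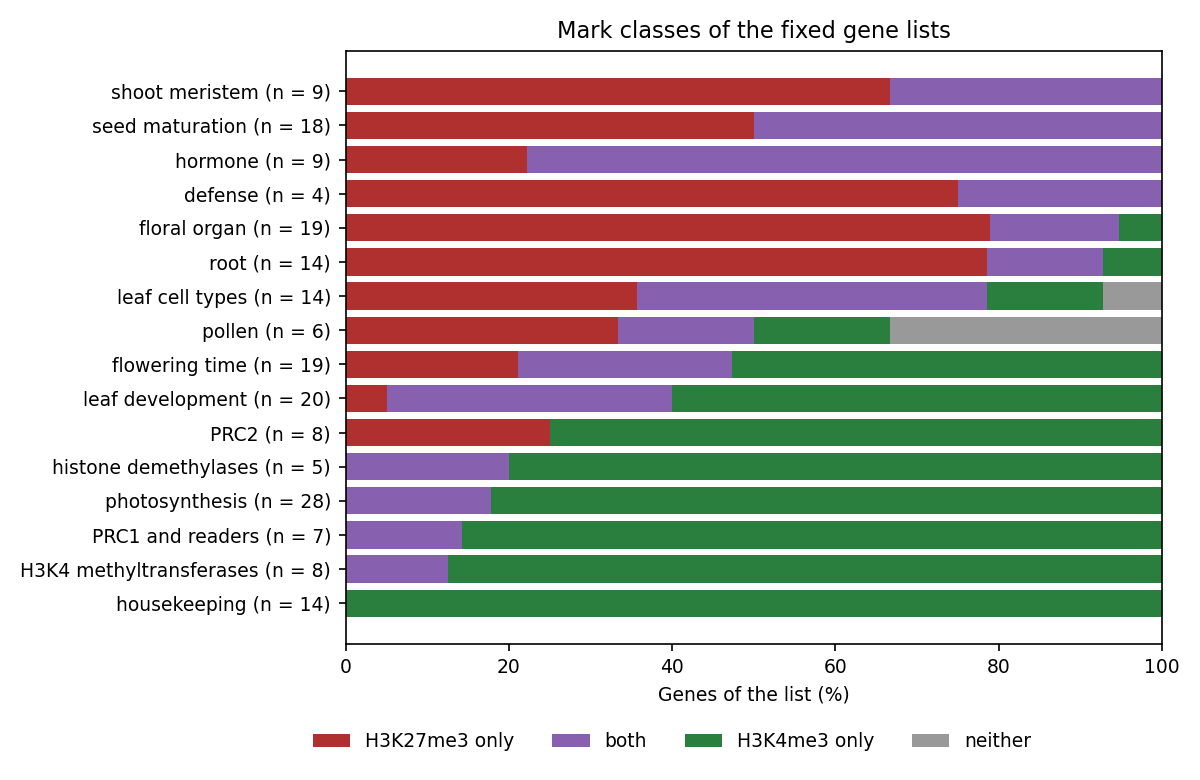
Percent of the genes of each fixed list in the 4 mark classes, with the number of genes in parentheses. Lists are ordered by the share with H3K27me3 (red and purple), from 0 of 14 housekeeping genes at the bottom to 9 of 9 shoot meristem genes at the top.

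Regulators of organs that a young leaf lacks mostly carried H3K27me3. Depth was not held constant in the tests of these lists or of the seed maturation list below. Most members of these lists were not listed in the mRNA table. Of all 7451 unlisted protein-coding genes, 4228 had H3K27me3 alone, 586 had both marks and 274 had H3K4me3 alone. The calls against all other genes therefore do not set these regulators apart from other unlisted genes. Of 19 floral meristem and organ identity genes, 18 had the mark (94.7%, exact adjusted p = 1.37e-07) and 15 had it alone. It covered the whole body of AG (AT4G18960), the stamen and carpel identity gene, with a depth of 1.41, and 98.8% of AP1, which was not listed. CAL and UFO, also not listed, had it alone. SEP4 (9.76), FUL (AGL8, 1.02) and LFY (not listed) carried both marks, and AP2 (5.96) was the only member with H3K4me3 alone. H3K4me3 was on 4 of the 19 (exact adjusted p = 0.000615), a call lost when domains had to cover at least 50% of the body (exact adjusted p = 0.15). All 9 shoot meristem and boundary genes had H3K27me3 (exact adjusted p = 0.000131), among them STM, KNAT1 and CLV3, which were not listed. The deepest were KNAT6 at 1.38 and KNAT2 (H3K27me3 alone) at 1.00, and KNAT6, WUS and CUC2 also carried H3K4me3. Of 14 root genes, 13 had H3K27me3 (exact adjusted p = 2.39e-05) and 3 had H3K4me3 (exact adjusted p = 0.00434). The root hair genes RHD6 and RSL4 lay wholly under H3K27me3 and were not listed, and EXPA7 was not listed either, with 81.6% under the mark. SCR (11.7), which also acts in leaves, had H3K4me3 alone, and SHR (4.40) and ESB1 (2.68) had both. The lower H3K4me3 share of root genes was not called at 50% of the body (exact adjusted p = 1) or among domains at or above the median score (exact adjusted p = 0.15). The 6 pollen genes did not pass the test for H3K27me3 (3 of 6, exact adjusted p = 0.521) or H3K4me3 (2 of 6, exact adjusted p = 0.309). DUO1 and AGL104 had neither mark, MGH3 lay wholly under H3K27me3 and was not listed, and the highest pollen depth was 1.00, for GEX2 and VGD1.

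All 18 seed maturation genes carried H3K27me3 (exact adjusted p = 2.03e-08), and 9 of them carried both marks. The latter included the storage protein genes CRA1, CRU3 and SESA1 to SESA4, which had 300 to 450 bases of H3K4me3 inside H3K27me3 and were not listed in the mRNA table. CRU2 (H3K27me3 alone) and LEC1 (both) were not listed either. DOG1, a regulator of seed dormancy, was the deepest at 4.71, followed by PHE1 at 1.39 with H3K27me3 alone. Among domains at or above the median score, 17 of the 18 kept H3K27me3 and 0 kept H3K4me3, and the lower H3K4me3 share was then called (exact adjusted p = 0.0023, against 0.334 for 9 of 18 with all domains).

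Photosynthesis and reference genes showed the opposite pattern. All 28 photosynthesis genes carried H3K4me3 (exact adjusted p = 6.46e-05), with depths from 464.5 for SBPASE and 864.3 for GAPB to 22244 for CAB1 and a median of 4183. H3K27me3 was also called on 5 of them, RBCS2B, CAB3, LHCB6, LHCA3 and PSAD-1 (exact adjusted p = 0.274), but on 0 among domains at or above the median score (exact adjusted p = 0.0058). All 14 housekeeping genes had H3K4me3 (exact adjusted p = 0.00993) and 0 had H3K27me3 (exact adjusted p = 0.0194). Their depths ran from 7.33 for AT4G34270 and 10.81 for AT2G28390 to 1004.7 for UBQ10 and 1029 for the elongation factor gene AT5G60390, with a median of 97.0. The H3K27me3 call was lost with 1 base as the limit (exact adjusted p = 0.17), with 50% of the body (0.15) and with domains at or above the median score (0.095), and the H3K4me3 call with 50% of the body (0.15). Depth was not held constant in these tests. H3K4me3 was on 96.1% to 98.5% of listed genes in the bins of depth from 6.92 upward, where the genes of both lists lie. Against lists matched on depth, H3K27me3 on housekeeping genes did not differ (two-sided p over random lists 0.195).

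Leaf polarity and growth genes mostly carried H3K4me3, and some carried H3K27me3 too. Regulators of single leaf cell types mostly carried H3K27me3, with H3K4me3 on 8 of 14 (exact adjusted p = 0.65). Of 20 leaf polarity and growth genes, all listed, 19 had H3K4me3 (exact adjusted p = 0.00993) and 8 had H3K27me3 (exact adjusted p = 0.561). PHB, PHV and REV, genes of the adaxial, upper leaf side, had H3K4me3 alone, and AS2 (2.09), also adaxial, had both marks. YAB1 (AFO, 12.3), YAB3 (11.7), KAN1 (6.01) and KAN2 (4.11) of the abaxial, lower side had both, as did YAB5 and ANT, and YAB2 (7.15) had H3K27me3 alone. No test compared the leaf sides. The 5 TCP genes had H3K4me3 alone, up to depths of 52.4 for TCP2 and 27.9 for TCP24. AS2 and GRF3 (2.45, H3K4me3 alone) were the shallowest. The H3K4me3 call was lost with 50% of the body (exact adjusted p = 0.81) and with domains at or above the median score (0.068). Depth was not held constant in this test. H3K4me3 was on 77.5% to 98.5% of listed genes in the bins of depth from 1.97 upward, where these genes lie. Regulators of single leaf cell types carried H3K27me3 more often than all other genes, on 11 of 14 (exact adjusted p = 0.00126), of which 6 carried both marks. Among listed genes, the difference from leaf polarity and growth genes did not pass (9 of 12 against 8 of 20, Fisher exact p = 0.076). These 6 were the stomatal genes SPCH, FAMA and EPF1, the trichome genes GL2 and GL3, and SUC2, the sucrose transporter of phloem companion cells, at a depth of 111.9. TTG1 (26.0) and TMM (5.25) had H3K4me3 alone, EPF2 (2.60) had neither, and MUTE (2.12), ATHB8 (4.47), APL (11.7), VND7 (1.47) and GL1 (not listed) had H3K27me3 alone. All 9 auxin and gibberellin genes had H3K27me3 (exact adjusted p = 0.000131), and 7 had both marks, among them TAA1 and GA3OX1 (5.22, the deepest). YUC1 and YUC4 had H3K27me3 alone and were not listed.

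Flowering time genes did not pass the test for H3K27me3 (9 of 19, exact adjusted p = 0.259) or H3K4me3 (15 of 19, exact adjusted p = 0.335). With domains at or above the median score the same share of 47.4% with H3K27me3 was called higher (exact adjusted p = 0.028). FT and TSF, which encode the mobile flowering signals, had H3K27me3 alone and were not listed. The floral repressor FLC (4.20) had H3K27me3 over 89.0% of its body and H3K4me3 over 4.94%, and SOC1 (AGL20, 19.8), MAF4, MAF5 and AGL19 also had both marks. SVP (49.1) and FLM (MAF1, 24.1) were the deepest, with H3K4me3 alone. CO had H3K4me3 alone and was not listed.

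The machinery of the marks itself mostly carried H3K4me3 alone, and none of its 4 lists passed the test. Of the 8 PRC2 subunits, 6 had H3K4me3 alone, with depths from 4.36 for CLF to 9.38 for SWN and 11.01 for MSI1. MEA and FIS2, which act in the seed, had H3K27me3 alone and were not listed. All 7 PRC1 and reader genes had H3K4me3 (exact adjusted p = 0.123), and EMF1 (3.68) also had H3K27me3 over 52.1% of its body. The shallowest were RING1B (1.37) and DRIP1 (2.90) and the deepest LHP1 (TFL2, 7.13) and VRN1 (8.12). All 8 genes of the list of H3K4 and H3K36 methyltransferases had H3K4me3 (exact adjusted p = 0.123), from ATX1 (1.97, both marks) and ATX4 (SDG16, 2.41) to ATXR3 (SDG2, 6.41) and ASHH2 (EFS, 8.55), known mainly for H3K36 methylation, as did all 5 demethylase genes (exact adjusted p = 0.28), where JMJ30 (JMJD5, 4.26) had both and ELF6 (5.59), JMJ18 (8.97) and JMJ14 (11.14) had H3K4me3 alone. The 4 defence genes were too few to test. All 4 had H3K27me3, and PR2 (BGL2, 13.6), PDF1.2 (5.79) and PR1 (1.15) had it alone, whereas PR5 (8.34) had both.

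List medians of depth were placed among 10000 random lists of the same size and gene length. Photosynthesis and housekeeping genes stood at percentile 100. Floral organ (0.005), root (0.305), shoot meristem (0.33), pollen (1.00) and seed maturation genes (1.84) stood in the lowest 2.5 percentiles, all with a median of 0. The other lists stood in between, at 4.87 for hormone genes (median 1.57), 9.70 for H3K4 and H3K36 methyltransferases (3.83), 14.5 for flowering time (3.60), 19.6 for PRC1 (3.68) and 41.7 for leaf cell types (4.19). Demethylases stood at 42.2 (5.84), PRC2 at 42.7 (5.98), leaf development at 64.1 (6.72) and defence at 84.7 (7.07).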

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

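The tests in this part were all chosen after the results were seen. Loci that are not protein-coding were outside the main comparisons and drew attention because the marks were present on them. H3K27me3 covered at least 150 bases of 43.99% of 3917 loci annotated as pseudogenes (95% interval 42.4 to 45.6), against 31.0% of protein-coding genes. Of these loci, 3062 lay in the gene-poorest 24 of the 1 Mb bins, where 40.7% (38.9 to 42.5) carried the mark. In the other groups of bins the share was 52.7% to 66.1%. The reference table does not set transposons apart, so how many of these loci are transposons was not determined. Of the 3917, 2 were listed in the mRNA table. Loci annotated as transcribed pseudogenes are a separate class of 926, with the mark on 41.3% (38.1 to 44.5) and 209 listed. The low number listed among the 3917 may therefore follow from the annotation. H3K27me3 was on 31.3% of 326 miRNA loci (26.3 to 36.6), against 31.0% of protein-coding genes. It was on 36.5% of the 203 that overlap no other annotated gene. MIR169c and MIR163 were among the widest. H3K4me3 was on 53.3% of 287 snoRNA loci (47.4 to 59.2), and on 54.7% of the 137 that overlap no other annotated gene. Length was not held constant between kinds of loci, and a longer body has more room for 150 covered bases. Shares of different kinds of loci are therefore not directly comparable. No control domain list was used here, so no background level was measured and these shares do not show how many of the calls are real.

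Many H3K27me3 domains touched no protein-coding gene, 6318 of 15863 (39.8%), and 4 of the 5 widest were of this kind. Of the 153 with 3000 bases or more, 71 lay in the gene-poorest bins. Regions where every library gathers reads would be called for H3K4me3 too, and H3K4me3 covered 3.35% of the bases of the 6318 domains (bootstrap interval 3.01 to 3.70), above its 0.977% of the other bases outside protein-coding gene bodies. That source stays open, although H3K4me3 touched only 452 of the 6318 (7.15%). Weak calls stay open as well: 31.7% (30.6 to 32.9) of the 6318 domains scored at or above the median, against 62.1% (61.2 to 63.1) of the other H3K27me3 domains. Part of this is width, which the score follows (median 600 against 900 bases), but against the median of domains of their own width the shares were still 35.7% (34.5 to 36.9) and 59.5% (58.5 to 60.5). The design holds no group that bears on a biological explanation, so none was tested.

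H3K27me3 was called more often on the most transcribed genes than on those of middle depth, at 22.5% (45 of 200 genes) against 8.99% (Fisher exact p = 1.8e-08). For these 200 genes weak calls may account for part of this. Among domains at or above the median score the shares were 7.50% (15 of 200, interval 4.26 to 12.1) and 4.05% (3.57 to 4.58). An excess remained (Fisher exact p = 0.028, not adjusted). With the median taken among domains of the same width, since the score follows width, the shares were 20 of 200 genes (interval from 6.22% to 15.02%) and 4.58% (Fisher exact p = 0.0018, not adjusted). The excess rests on 15 and 20 genes, in groups chosen after the data were seen. Fisher's exact test treats neighbouring genes of 1 mRNA library as independent. The score does not show how far a domain lies from the caller's limit. Whether weak calls account for the whole excess on these 200 genes therefore stays open. The 28 photosynthesis genes had no H3K27me3 at or above the median score. For the 800 genes between the 95th and 99th percentile of depth the values were mixed: 16.25% had H3K27me3 with all domains, 4.88% (3.49 to 6.60) at or above the median score (Fisher exact p = 0.26 against middle depth) and 7.25% (5.55 to 9.27) at or above the median of the same width (Fisher exact p = 0.0017), so whether weak calls account for the whole excess there stays open. A spill of H3K4me3 signal or open chromatin into the H3K27me3 calls also stays open. On the 45 of the 200 genes with H3K27me3, 75.2% of the H3K27me3 bases lay under H3K4me3. Of the bodies of these 45 genes, 65.8% lay under H3K4me3, a difference of 9.46 points (bootstrap over the 45 genes, -1.57 to 21.7). No biological explanation was tested.

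Genes with both marks numbered 2785. Edges of neighbouring domains that touch on a gene are not the whole cause, because 55.7% of these genes (53.9 to 57.6) had over 300 bases, 1 H3K27me3 window, under both marks. Weak calls as an explanation for part of the class stay open, with mixed values: with domains at or above the median score, 57.8% (56.0 to 59.7) of these genes kept H3K27me3 and 31.4% kept H3K4me3, against 75.5% (74.4 to 76.6) of the genes with H3K27me3 alone and 60.4% of those with H3K4me3 alone. With the median taken among H3K27me3 domains of the same width, 64.0% (62.2 to 65.8) and 62.8% (61.5 to 64.0) kept H3K27me3, so the H3K27me3 difference went with narrower domains, and whether narrow calls are weak calls was not tested. A mixture of leaf cells, some with either mark, would put H3K27me3 on transcribed regulators of single cell types. Of the listed members of the leaf cell type list, 75% (9 of 12) had it. This was above 41.7%, the upper 95% bound over random lists matched on depth. SUC2 (111.9) was the most abundant, TTG1 (26.0), the next, lacked the mark, and 0 of the genes stood in another list. Among the 9, MUTE, ATHB8, APL and VND7 had H3K27me3 alone, so this count covers H3K27me3 and not both marks together. Leaf development (8 of 20), flowering time (7 of 16, above 37.5%) and hormone genes (7 of 7) also exceeded their matched lists. Housekeeping (0 of 14) and photosynthesis genes (5 of 28) did not differ from theirs (two-sided p over random lists 0.195 and 0.782). Cell type genes did not pass a test against leaf development genes (Fisher exact p = 0.076). A mixture of cells therefore stays open beside H3K27me3 on regulators in general.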

How the results depend on the processing

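No paired analysis was possible because each mark has 1 domain list for the series and the mRNA has 1 library, so replicates were not separate; leaving out a replicate, a gene start inside a domain (no strand), a minimum of 10 reads and unscaled counts (only depths were given) were not run. Alternatives with an older name, a depth of at least 2 or H3K27me3 domains of at least 600 bases were chosen after seeing the data. No tested result reversed under any alternative run, but the untested order of genes with both marks and neither mark turned with 50% of the gene body, at medians of 2.92 and 4.58 and 77.8% and 81.5% listed (2.36 and 0, 79.0% and 41.8% as reported). The association of the marks and their shared bases kept direction under each, with the smallest p that shifts can give in every shift test. With at least 50% of the gene body covered, genes with H3K4me3 alone numbered 3854, both 410 and neither 17523, the mean log2 difference between H3K4me3-only and H3K27me3-only genes was 3.73, the difference in share listed 66.6 points, and 1 list in place of 5 was called for H3K4me3; H3K4me3 seldom covers 50% of a body, so this limit removes calls by construction. With domains at or above the median score these values were 9594, 276, 11926, 3.35 and 65.2, and 230 H3K4me3 domains touched H3K27me3; fewer domains entered, and why the class with both marks fell most was tested only in part. Without genes that overlap another gene, 9647 genes had H3K4me3 alone, with differences of 3.13 and 74.6. Genes with an older name left 2393 with neither mark and a difference of 70.6 points. A depth of at least 2 gave 81.7 points, listed genes only a log2 difference of 1.92, and a pseudocount of 0.1 gave 5.43, as low values are stretched. Spearman rho with depth was 0.69 for H3K4me3 and -0.50 for H3K27me3 with the share of the body, and 0.56 and -0.27 among listed genes. Of 60 checks of the 12 list calls, 51 kept the call: all 12 under the shift test and with H3K27me3 domains of at least 600 bases, 11 with 1 base, 9 with domains at or above the median score and 7 with 50% of the body. The 6 lists with more H3K27me3 kept it throughout. Within the classes, 14 of 28 medians of depth and 16 of 24 shares listed moved beyond their interval; H3K27me3 alone kept a median of 0. ChIP and mRNA read numbers are unknown, so whether unlisted genes are silent or under the depth of this library is open.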

Other observations

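The test of neighbouring genes and the test of gene families were written before their results were seen, and other choices in this part came after. Gene families picked by symbol differed widely in H3K27me3. Fisher's exact test, adjusted over 42 tests (21 families, both marks), called 11 families higher and 3 lower for H3K27me3. Genes named MYB had the mark in 66.4% of 125 cases (exact adjusted p = 7.4e-15) and genes named WOX in 11 of 14 (exact adjusted p = 0.00094). NAC genes stood at 54.0% (exact adjusted p = 1e-05) and WRKY genes at 53.5% (exact adjusted p = 0.0003). Of 8 transcription factor families, 7 were higher, and ARF-named genes, which may include ADP-ribosylation factors beside auxin response factors, were lower at 1 of 25 (exact adjusted p = 0.0048). Outside the regulators, genes named CYP, cytochrome P450 enzymes of specialised metabolism among other tasks, had H3K27me3 in 61.5% of 234 cases (exact adjusted p = 1.9e-20) and UGT glycosyltransferases in 53.1% of 64 (exact adjusted p = 0.00094). Ribosomal protein genes named RPL or RPS carried H3K4me3 in 56 of 56 cases (exact adjusted p = 2.3e-10) and H3K27me3 in 2 (exact adjusted p = 3.6e-06). Photosystem genes named PSA or PSB carried H3K4me3 in 27 of 27 (exact adjusted p = 3.4e-05) and H3K27me3 in 2 (exact adjusted p = 0.015). H3K4me3 was lower in genes named NAC (41.0%, exact adjusted p = 1.2e-05), MYB (28.8%, exact adjusted p = 7.4e-15) and CYP (50.9%, exact adjusted p = 9.8e-05) than in about 64.5% of other genes, and higher in the plant U-box genes named PUB (91.3%, exact adjusted p = 0.016). The 7 families without a call for H3K27me3 included PUB (13.0%), receptor-like proteins (26.9%), cysteine-rich receptor kinases (29.5%) and ABC transporters (36.2%). Copies of a family can be tandem neighbours, which this test treats as independent. Depth was not held constant either. Median depth was 0 to 2.46 for the WOX, MYB, NAC, CYP, WRKY and UGT genes. It was 5.79 for ARF, 106.0 for RPL or RPS and 1800 for PSA or PSB genes. Among all listed genes, H3K27me3 was on 51.9% of the shallowest 10%, 8.99% between the 50th and 80th percentile and 22.5% of the 200 deepest. How far the family shares follow depth was not tested.

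Genes with H3K27me3 sat next to each other. There were 4034 adjacent pairs of protein-coding genes with the mark, against a mean of 2631 and a highest value of 2756 when labels were permuted within chromosomes 1000 times. Pairs without a domain across the gap between the genes numbered 3348, against a mean of 2242 and a highest value of 2347, so domains that span both genes are not the only source of the excess. A candidate explanation is that H3K27me3 marks clusters of related genes, and gene-poor and gene-rich regions, which were not held constant, could add to it. The longest run held 24 genes on chromosome 3, from CYCP2;1 to AT3G22060, of which 4 were listed in the mRNA table. A run of 16 genes on chromosome 4 held PEN1, BARS1 and the cytochrome P450 genes CYP705A1 to CYP705A4, a cluster of triterpene synthesis, with 3 genes listed.

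Some genes with a depth in the mRNA table lacked an H3K4me3 call. Depths of 10 or more were found for 108 genes with H3K27me3 alone and 88 with neither mark. TGG1 and TGG2 had depths of 1029 and 371.3 under H3K27me3 over nearly the whole body. AT2G01021 and AT5G35480 had depths of 297.4 and 281.3 without either mark.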
